A study of Saccharomyces cerevisiae with 11 samples.

How the data were processed

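Ribosome footprints and mRNA were measured in 2 Saccharomyces cerevisiae strains whose genomic rDNA is depleted, so that rRNA comes from a plasmid only, per the series description. One plasmid carries the wild-type (WT) rRNA sequence and the other lacks expansion segment ES7S of the 18S rRNA (ΔES7S), as the condition field of each sample states. The parent strain is named differently in the series description and in the samples' source fields, which are alike for both groups. The 11 libraries analysed here were 3 WT and 3 ΔES7S footprint libraries (replicates 1 to 3 each), 2 WT mRNA libraries (replicates 2 and 3) and 3 ΔES7S mRNA libraries (replicates 1 to 3). WT mRNA replicate 1 was not analysed here. The labels do not say whether replicates were separate cultures, so that the p-values below measure the spread between these samples.

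Per the labels' protocols, cells were grown in YPD, snap-frozen and ground in a cryomill. For footprints, lysates were digested with RNase I and 80S ribosomes were taken from a density gradient. For mRNA, RNA was extracted with hot acid phenol, enriched on oligo-dT beads and randomly fragmented. Fragments of 24 to 28 nt were size-selected, ligated to adapters, circularised, reverse transcribed and amplified in 4 to 8 PCR cycles, and no molecular identifiers are named. The labels name FastQC 0.11.7 and Bowtie 1.2.3. The genome build, the annotation, the counting tool and its handling of strand and of reads that fit several genes are not given in the sources used here.

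The authors deposited 1 table of raw read counts per gene for each library, with no normalisation, listing genes with at least 1 count. A gene absent from a table was taken as 0. Total counts ran from 5712239 to 57968667 per library. Of 5756 genes listed in any library, 5752 were matched by systematic name to the gene table used for symbols, 4 were not, and 5501 were listed in every library. Libraries were checked for duplicates: within groups, the chi-square per degree of freedom between libraries ran from 27.5 to 241 for genes with at least 20 counts. Counting error is small at these depths next to the spread between replicates, and it does not cover PCR copies, which were counted without molecular identifiers.

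Counts were analysed in R 4.3.3 with edgeR 4.0.16 (filterByExpr on the groups, TMM normalisation, estimateDisp, glmQLFit with robust=TRUE, glmQLFTest). There were 3 comparisons, each ΔES7S minus WT: footprints (6 libraries), mRNA (5 libraries), and translation efficiency, the interaction of assay and strain in 1 model over all 11 libraries with 1 mean per group. P-values are two-sided quasi-likelihood F-tests adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The error given for a log2 fold change (SE) is its absolute value divided by the square root of F. CPM are counts scaled to the total of each library, taken over all its counts without TMM factors (which ran from 0.835 to 1.10), so that a ratio of mean CPM can differ from the fitted fold change. Their errors are SD over the libraries of a group (n = 3, and n = 2 for WT mRNA). List levels and list tests use TMM-scaled log2 CPM. Changes are relative to the other genes of a library, since no spike-in is named.

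Before the data were examined, 33 gene lists, the rule for named genes, the tests and the alternatives were fixed. The lists were 40S, 60S and mitochondrial ribosomal proteins; 40S and 60S subunit assembly factors; RNA polymerase I and III; translation initiation factors; translation elongation and termination factors; aminoacyl-tRNA synthetases; ribosome quality control and mRNA decay; glycolysis and fermentation; the TCA and glyoxylate cycle; respiratory chain and ATP synthase; heat shock chaperones; the induced environmental stress response; proteasome; ER protein folding; amino acid biosynthesis (Gcn4 targets); methionine and sulfur assimilation; ergosterol biosynthesis; the iron and phosphate regulons; glucose-repressed hexose transport and alternative sugars; core histones; G1 and S phase cell cycle; cell wall integrity; a-cell, alpha-cell and haploid mating genes; meiosis and sporulation genes; auxotrophic and plasmid markers; genes with a programmed frameshift or leader ORF; and secreted and GPI-anchored proteins. The heat shock list holds cytosolic and mitochondrial chaperones. Each list with at least 5 members tested was tested against all other genes with camera (limma 3.58.1) on log2 CPM (prior count 2), at a preset correlation of 0.01, two-sided, Benjamini-Hochberg over 32 lists. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance one way, were run as alternatives.

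Named genes were the 10 largest rises and 10 largest falls per comparison among genes with an adjusted p under the threshold and an average log2 CPM of at least 4. For footprints and mRNA every ΔES7S library also had to lie on the same side of every WT library. Chance meets this condition for 10% of genes with 3 libraries against 3 (footprints), and for a larger share with 3 against 2 (mRNA). For translation efficiency the sign had to hold whichever library was left out. Up to 4 members of each list with the smallest p were added, and for lists without a changed member the 2 of highest abundance. Some genes that this rule names are not reported here. Marker lists are given in every library. Near-identical gene copies (many ribosomal protein pairs, TDH2 and TDH3, TEF1 and TEF2, the histone genes, IMD2 to IMD4, HXT6 and HXT7) share reads, and their values depend on the counting rule.

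The pipeline was tested on simulated counts with known changes. At a 2-fold change it recovered 94.0% of changed genes in footprints, 67.2% in mRNA and 46.3% in translation efficiency. At 1.5-fold it recovered 59.7%, 11.9% and 7.46%. The share of false calls was 2.33%, 6.35% and 2.91%. The simulation changed 200 genes, gave each unchanged gene 1 mean over all libraries of a comparison, both assays included, and held no variation shared between genes. Recovery and false calls in the real data can differ from these shares. The list that was moved was found in each comparison and 0 other lists were called by camera at the preset correlation; simulated genes varied independently, so that this did not test that correlation.

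The alternatives were median-of-ratios (RLE) and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no count filter, at least 10 counts in every library, a 2-fold minimum, a replicate block, a culture block, exclusion of ribosomal protein genes, 1 joint fit, and each library left out in turn. Library similarity was computed on log2 CPM over genes with a mean of at least 30 CPM. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.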

Results

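Ribosome-protected fragments (footprints) and poly(A)-enriched mRNA were sequenced from yeast that lives on plasmid-borne rRNA, either with the wild-type sequence (WT) or without ES7S (ΔES7S), an expansion segment of the 18S rRNA of the small ribosomal subunit. The footprint libraries held 8103654, 20262647 and 15880513 counts in WT replicates 1 to 3 and 14170578, 14171383 and 5712239 in ΔES7S replicates 1 to 3. The mRNA libraries held 43581601 and 57968667 counts in WT replicates 2 and 3 and 32081744, 18953306 and 17981273 in ΔES7S replicates 1 to 3. Each library listed between 5567 and 5732 genes, and the 10 most abundant genes took between 9.0% and 14.8% of its counts.

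The assay separated the libraries first: principal component 1 of all 11 libraries held 77.3% of the variance and parted footprints from mRNA. Across genes (4237 with a mean of at least 30 CPM, not independent replicates), log2 CPM correlated with r = 0.989 between the WT mRNA libraries and r from 0.988 to 0.991 between WT footprint libraries. The ΔES7S libraries varied more, with r from 0.956 to 0.982 in mRNA and from 0.955 to 0.985 in footprints. Cytosolic ribosomal protein genes took 5.38% to 5.52% of footprint counts in WT, but 11.2%, 8.07% and 5.43% in ΔES7S replicates 1, 2 and 3. Their share of mRNA counts was 10.7% and 13.1% in WT and 14.7%, 16.8% and 13.3% in ΔES7S.

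The first comparison asks which genes had more or fewer footprints in ΔES7S cells, relative to other genes and without regard to their mRNA. Footprints fell on the genes that build ribosomes: of 149 assembly factor genes for the 40S and 60S subunits, 114 fell and 0 rose, with a median log2 fold change of -0.64. Of 49 stress response genes 23 rose and 0 fell, and of 54 amino acid biosynthesis genes under the transcription factor Gcn4 21 fell and 2 rose. These lists were called by camera at the preset correlation, and with an estimated correlation their adjusted p ran from 0.698 to 0.792. Single genes that rose were HXK1 (YFR053C, hexokinase 1) at 4.33-fold, GSY1 (YFR015C, glycogen synthase) at 3.36-fold and PGM2 (YMR105C, phosphoglucomutase) at 3.15-fold, and LYS20 (YDL182W, homocitrate synthase) fell 2.93-fold. Over all 5442 genes tested, edgeR called 1463 at an adjusted p under 0.05, 775 higher and 688 lower in ΔES7S, and 96 and 81 of these by at least 2-fold (2131 had an unadjusted p under 0.05). With upper-quartile scaling 702 were higher and 746 lower. Without WT replicate 2, WT replicate 3 or ΔES7S replicate 2 the number of genes was 916, 684 or 740.

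Of 75 tested assembly factors of the 40S subunit, 61 fell, 0 rose and 14 did not pass the test (64 fell when adjusted over the list alone). Of 74 for the 60S subunit, 53 fell, 0 rose and 21 did not pass, and 61 fell when adjusted over the list alone. FAF1 fell the most of the 40S members named (from 53.8 ± 9.40 to 17.9 ± 1.41 CPM, SD, n = 3 each; log2 fold change -1.50 ± 0.14, SE; adjusted p = 0.000325), followed by the helicase HCA4 at -1.13 ± 0.12 (adjusted p = 0.000366). In the 60S list the helicase DBP7 had -1.14 ± 0.12 (adjusted p = 0.000441) and RRS1 -0.97 ± 0.11 (adjusted p = 0.000685). NSR1, the yeast nucleolin, which is in neither list, fell from 477 ± 96.2 to 149 ± 14.8 CPM (-1.60 ± 0.15, adjusted p = 0.000356). The list medians were -0.67 and -0.61, with camera adjusted p = 5.17e-21 and 6.58e-19, and adjusted p = 0.698 for both with an estimated correlation. By fry the adjusted p was 0.0362 and 0.0369. The mean level of the 40S list lay at -0.64 ± 0.12 relative to WT in ΔES7S (SD over 3 libraries; WT SD 0.15), and that of the 60S list at -0.58 ± 0.12 (WT SD 0.15). Without WT replicate 3 or ΔES7S replicate 2, 35 members of the 60S list passed. RNA polymerase I and III, which transcribe rRNA and tRNA, had 11 of 36 genes lower, 2 higher and 23 not past the test (the same counts adjusted over the list alone). The largest polymerase I subunit RPA190 had -0.70 ± 0.14 and the TFIIIC subunit TFC3 0.46 ± 0.10. The median was -0.20, with adjusted p = 0.0123, adjusted p = 0.792 with an estimated correlation, and p = 0.0505 without WT replicate 3.

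Cytosolic ribosomal protein genes went the other way, but unevenly between the ΔES7S libraries. Of 57 genes of the 40S subunit 17 rose, 0 fell and 40 did not pass (24 rose when adjusted over the list alone). Of 81 of the 60S subunit 19 rose, 0 fell and 62 did not pass (6 rose when adjusted over the list alone). RPS1B had 1.25 ± 0.27 (adjusted p = 0.00924), RPS9B 1.07 ± 0.22, RPL32 1.49 ± 0.29 (adjusted p = 0.00605) and RPP2B 1.33 ± 0.23. Many of these genes have a near-identical copy, RPL32 has none. Both medians were 0.66, with camera adjusted p = 1.05e-06 and 4.17e-08, and adjusted p = 0.792 for both with an estimated correlation. The mean level of the 40S list relative to WT was 1.08, 0.63 and -0.03 in ΔES7S replicates 1, 2 and 3, and that of the 60S list 1.15, 0.67 and -0.05, against WT SD of 0.01 and 0.02. Without ΔES7S replicate 3, 52 and 72 genes rose, and without replicate 1 the medians were 0.35 with 12 and 14 genes higher. Without ΔES7S replicate 2, 5 genes of each list rose, and without 1 of the WT libraries 2 to 6.

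Of 49 genes of the induced environmental stress response 23 rose, 0 fell and 26 did not pass (23 rose when adjusted over the list alone), with a median of 0.45, adjusted p = 1.05e-06 and adjusted p = 0.792 with an estimated correlation. GSY1 went from 20.9 ± 4.08 to 65.8 ± 9.15 CPM (SD, n = 3 each; log2 fold change 1.75 ± 0.16, adjusted p = 0.000325) and PGM2 from 144 ± 36.6 to 432 ± 68.9 CPM (1.66 ± 0.21, adjusted p = 0.001). TPS1, trehalose-6-phosphate synthase, had 1.29 ± 0.18 (adjusted p = 0.00126). Without ΔES7S replicate 2 the number of members that rose was 15. Of 28 heat shock chaperones 10 rose, 0 fell and 18 did not pass (10 rose when adjusted over the list alone; median 0.43, adjusted p = 8.89e-05, and 0.792 with an estimated correlation). The small heat shock protein HSP42 rose from 257 ± 46.1 to 668 ± 159 CPM (1.45 ± 0.21, adjusted p = 0.0013). The Hsp90 cochaperone AHA1 had 1.16 ± 0.14, and BTN2, a protein sorting factor induced by stress, rose 3.30-fold. The chaperone median ran from 0.28 (without WT replicate 3) to 0.65 (without WT replicate 1). These lists varied among WT libraries as well, with an SD of 0.23 and 0.29, and ΔES7S libraries lay between 0.19 and 0.77, and between 0.18 and 0.69, relative to the WT mean. WT replicate 1 lay at 0.18 for the stress response, just under ΔES7S replicate 1, and at 0.30 for the chaperones, above ΔES7S replicate 1. Within ΔES7S the share of footprint counts on ribosomal protein genes moved with these lists in reverse, 11.2% in ΔES7S replicate 1 and 5.43% in replicate 3.

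Of 54 amino acid biosynthesis genes 21 fell, 2 rose and 31 did not pass (22 fell and 2 rose when adjusted over the list alone), with a median of -0.32, adjusted p = 1.27e-06, adjusted p = 0.698 with an estimated correlation and 0.0227 by fry. LYS20 fell from 272 ± 44.3 to 88.7 ± 21.6 CPM (SD, n = 3 each; -1.55 ± 0.18, adjusted p = 0.000765). CPA1 (arginine synthesis) had -0.85 ± 0.11, and HIS4 -0.69 ± 0.12. The regulator GCN4 itself fell from 285 ± 64.3 to 102 ± 18.9 CPM (-1.41 ± 0.18, adjusted p = 0.00103). Without WT replicate 2, WT replicate 3 or ΔES7S replicate 2, 9 members fell. Of 19 genes with a programmed frameshift or a leader ORF, a list that shares GCN4 and CPA1, 7 fell, 2 rose and 10 did not pass (the same adjusted over the list alone). HAP4, a respiratory regulator, had -0.80 ± 0.11. The list's median was -0.17, with adjusted p = 0.0277, adjusted p = 0.698 with an estimated correlation, and 0.062 without ΔES7S replicate 1. Of 23 methionine and sulfur genes 3 fell (MET5, MET3 and MET1, with MET3 at -1.29 ± 0.39), 0 rose and 20 did not pass, and 0 passed when adjusted over the list alone by edgeR. The median was -0.30, with adjusted p = 0.0401, adjusted p = 0.88 with an estimated correlation, 0.177 without WT replicate 2 and 0.276 without ΔES7S replicate 1. The median ran from -0.12 (without ΔES7S replicate 1) to -0.54 (without ΔES7S replicate 3). Of 10 core histone genes, many with a near-identical copy, 6 rose, 0 fell and 4 did not pass (7 rose when adjusted over the list alone), among them HHF1 (histone H4) at 1.38 ± 0.21 and HTZ1 (H2A.Z) at 0.72 ± 0.14. Their median was 0.58, with adjusted p = 0.00799 and adjusted p = 0.792 with an estimated correlation, and 3 or 2 members rose without WT replicate 2 or 3.

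Camera called 4 more lists. Of 25 cell wall integrity genes 6 rose, 0 fell and 19 did not pass (6 adjusted over the list alone; chitin synthase CHS3 0.83 ± 0.12; median 0.24, adjusted p = 0.0143, and 0.792 with an estimated correlation). Of 27 genes for secreted and GPI-anchored proteins 8 rose, 1 fell and 18 did not pass (9 and 1 adjusted over the list alone; acid phosphatase PHO5 1.37 ± 0.17; median 0.24, adjusted p = 0.0401, and 0.792 with an estimated correlation). Of 69 mitochondrial ribosomal protein genes 10 fell, 4 rose and 55 did not pass (8 and 4 adjusted over the list alone; NAM9 -0.61 ± 0.10, MRP21 0.56 ± 0.10; median -0.18, adjusted p = 0.009, and 0.792 with an estimated correlation). Of 27 TCA and glyoxylate cycle genes 4 fell, 1 rose and 22 did not pass (3 and 1 adjusted over the list alone; cytosolic malate dehydrogenase MDH2 0.64 ± 0.14; median -0.18, adjusted p = 0.0314, and 0.698 with an estimated correlation). Each of these 4 lists lost its call without at least 1 library. Cell wall integrity lost it without WT replicate 3 (adjusted p = 0.0505) or ΔES7S replicate 1 (0.0736). Secreted proteins lost it without WT replicate 1 (0.0683), WT replicate 3 (0.133), ΔES7S replicate 1 (0.11) or ΔES7S replicate 2 (0.0754). The mitochondrial list lost it without WT replicate 1 (0.0513) or ΔES7S replicate 3 (0.142), and the TCA list without WT replicate 2 (0.0914) or ΔES7S replicate 1 (0.0736).

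Footprint falls outside the lists were led, among genes with an average log2 CPM of at least 4, by SEO1 (YAL067C, a putative permease) from 34.6 ± 3.75 to 6.29 ± 2.91 CPM (SD, n = 3 each; log2 fold change -2.48 ± 0.27, adjusted p = 0.000791) and IMD2 (YHR216W, IMP dehydrogenase) from 2203 ± 244 to 435 ± 117 CPM (-2.27 ± 0.22, adjusted p = 0.000356). IMD2 shares much of its sequence with IMD3 and IMD4. SPS100, GRE1, SIP18, PMA2 (a plasma membrane proton pump), AQR1 (a multidrug transporter) and YCL048W-A fell by between 1.66 and 2.19 on the log2 scale, with adjusted p from 0.00515 to 0.0395. Of these, SPS100 is a member of the meiosis and sporulation list. Among rises outside the lists above, YJR149W had 2.10 ± 0.17, YPC1 (ceramidase) 1.66 ± 0.12, RGI1 1.64 ± 0.21, RFS1 1.62 ± 0.14, YLR177W 1.60 ± 0.16 and GIP2 (a phosphatase subunit of glycogen control) 1.58 ± 0.19, with adjusted p from 0.000235 to 0.00124.

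In lists not called by camera in footprints, counts of genes higher and lower were 2 and 2 of 33 for initiation factors (eIF4G gene TIF4631 -0.65 ± 0.14) and 3 and 7 of 32 for elongation and termination factors (TEF2 1.56 ± 0.22, near-identical to TEF1; DPH2 -1.16 ± 0.14). Aminoacyl-tRNA synthetases had 1 and 2 of 21 (GRS1 0.64 ± 0.15), and ribosome quality control and mRNA decay 3 and 6 of 37 (FAP1 -1.35 ± 0.14). They were 3 and 4 of 21 for glycolysis (TDH2 -1.36 ± 0.12, with a near-identical copy in TDH3) and 3 and 0 of 40 for respiratory chain and ATP synthase (CYC7 0.84 ± 0.14). The proteasome had 1 and 0 of 35 (PRE7 0.46 ± 0.14), and ER protein folding 3 and 4 of 28 (DER1 0.69 ± 0.14; ULI1 -2.63 ± 0.28). They were 0 and 2 of 26 for ergosterol synthesis (ERG3 -0.71 ± 0.13), 1 and 3 of 25 for the iron regulon (ARN1 -0.96 ± 0.17) and 4 and 4 of 18 for the phosphate regulon (PHO5 1.37 ± 0.17; PHM6 -1.68 ± 0.25). Hexose transport had 2 and 1 of 19 (HXT7 1.94 ± 0.35, near-identical to HXT6), G1 and S phase genes 1 and 3 of 33 (CLN2 -0.61 ± 0.14), and meiosis genes 3 and 1 of 16 (HOP1 1.88 ± 0.26). Camera adjusted p for these lists ran from 0.16 to 0.965. The numbers of changed genes in these 14 lists ran from 0 to 10 when adjusted over the list alone.

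**Figure D1:**
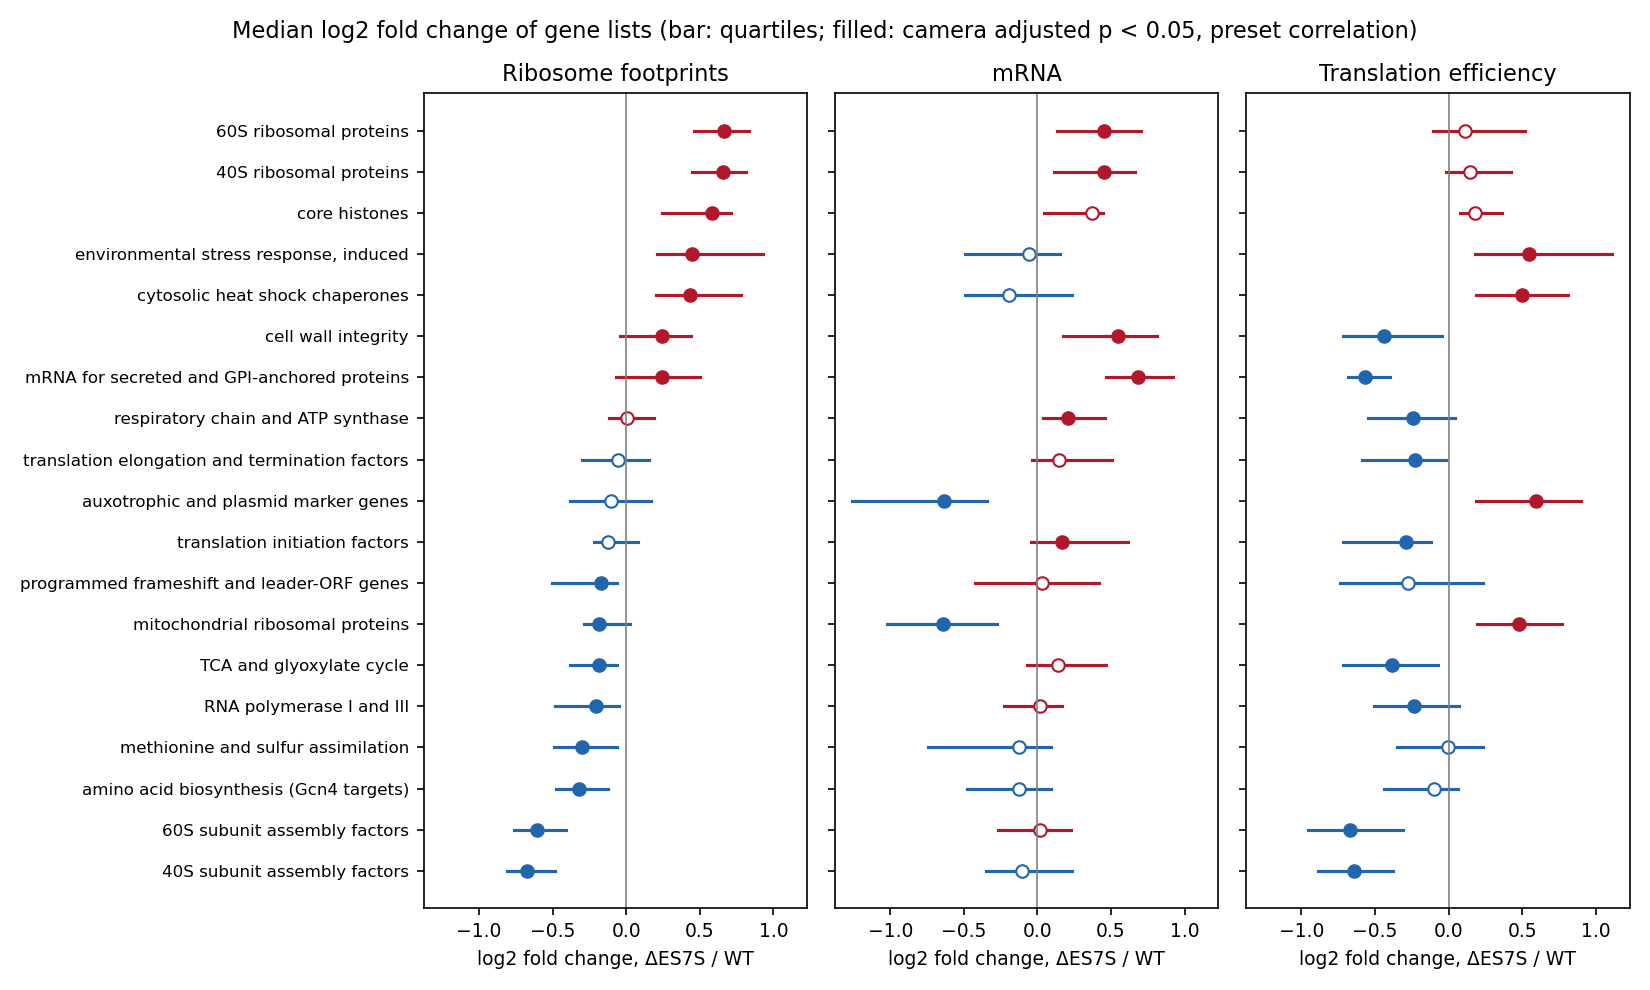
Median log2 fold change, ΔES7S over WT (x axis), of the gene lists called by camera in at least 1 comparison, in footprints, mRNA and translation efficiency; bars span the quartiles of each list, red and blue give the sign of the median, and filled points have an adjusted p under 0.05 at the preset correlation (0 lists with an estimated correlation). Assembly factors of the 40S and 60S subunits sit at -0.67 and -0.61 in footprints and at -0.11 and 0.02 in mRNA, and the 60S mRNA value turns to -0.06 with upper-quartile scaling.

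The second comparison asks which mRNAs differed in abundance. The mRNAs of mitochondrial ribosomal proteins were lower in ΔES7S: 21 of 69 fell and 0 rose, with a median log2 fold change of -0.64, and MRPL35 (YDR322W) fell 3.31-fold. Of the mRNAs of secreted and cell wall proteins 2 of 27 and 1 of 26 rose and 0 fell, with medians of 0.68 and 0.55, and the mannoprotein gene TIP1 (YBR067C) was up 3.83-fold. These 3 lists were called by camera at the preset correlation, and with an estimated correlation their adjusted p ran from 0.811 to 0.887. The iron-siderophore mannoprotein genes FIT3 (YOR383C) and FIT2 (YOR382W) rose 3.78-fold and 2.64-fold, and RPS9A (YPL081W), 1 of the 2 genes for ribosomal protein uS4, fell 4.33-fold. Over 5611 genes tested, edgeR called 155, 67 higher and 88 lower, and 36 and 59 by at least 2-fold (1727 had an unadjusted p under 0.05). With 2 WT libraries the number of genes rested on single libraries and on the tool: edgeR called 0 without WT replicate 2 or 3 or ΔES7S replicate 2 or 3 (660, 766, 1344 and 1034 at an unadjusted p under 0.05) and 2467 without ΔES7S replicate 1. With all libraries DESeq2 called 1036, limma-voom 327 and edgeR 1463 in a joint fit with the footprint libraries. Each count of mRNA list members below is likewise 0 in those 4 fits.

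Of the 69 mitochondrial ribosomal protein mRNAs 48 did not pass. With adjustment over the list alone 44 fell and 1 rose. MRPL35 went from 121 ± 11.3 (SD, n = 2) to 32.5 ± 12.9 CPM (SD, n = 3; log2 fold change -1.73 ± 0.23, SE; adjusted p = 0.0355 by edgeR). RSM19, MRP20 and MRP10 had -1.52 ± 0.20, -1.51 ± 0.24 and -1.49 ± 0.25 at the same adjusted p. Camera gave adjusted p = 2.21e-13, adjusted p = 0.811 with an estimated correlation, and fry 0.0517. The list's mean level lay between -0.83 and -0.58 relative to WT in the 3 ΔES7S libraries (WT SD 0.03), and its median between -0.61 and -0.68 whichever library was left out. Other mitochondrial genes that fell were OXA1, the inner membrane insertase, from 159 ± 6.86 to 43.1 ± 22.0 CPM (-1.73 ± 0.29), IBA57 (iron-sulfur cluster assembly, -1.87 ± 0.36, adjusted p = 0.0444) and SDH7 (succinate dehydrogenase assembly, -1.55 ± 0.23). The respiratory chain and ATP synthase list had a median of 0.21 (1 of 40 rose, ATP1 at 1.09 ± 0.22, 0 fell, 39 did not pass, and 0 passed by edgeR when adjusted over the list alone), with adjusted p = 0.00515 and adjusted p = 0.887 with an estimated correlation. GPP1, glycerol-3-phosphatase, fell from 586 ± 19.9 to 154 ± 43.7 CPM (-1.76 ± 0.19), and NPP2, a nucleotide pyrophosphatase, had -1.68 ± 0.30.

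Of 27 mRNAs for secreted and GPI-anchored proteins 2 rose, 0 fell and 25 did not pass, and 8 rose when adjusted over the list alone. TIP1 rose from 411 ± 63.0 (SD, n = 2) to 1352 ± 220 CPM (SD, n = 3; 1.94 ± 0.28, adjusted p = 0.0355 by edgeR) and PHO5 had 1.30 ± 0.18. The median was 0.68, with adjusted p = 5.26e-08 and adjusted p = 0.887 with an estimated correlation. Of 26 cell wall integrity mRNAs, 11 of which are also in that list, 1 rose (CHS3, 1.11 ± 0.18), 0 fell and 25 did not pass (4 rose when adjusted over the list alone; median 0.55, adjusted p = 5.29e-05, and 0.811 with an estimated correlation). FIT3 went from 27.9 ± 1.21 to 91.2 ± 6.98 CPM (1.92 ± 0.20) and FIT2 from 31.7 ± 3.15 to 72.3 ± 12.9 CPM (1.40 ± 0.23). The iron list as a whole had 2 of 28 higher, 5 higher and 1 lower adjusted over the list alone, a median of 0.28 and adjusted p = 0.101. Further named rises were YBL071C-B, CSS1, YBR287W, RIM4, COS111, PCA1 and FUR4 (uracil permease), with log2 fold changes from 1.33 to 2.15 and adjusted p from 0.0355 to 0.0429.

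Ribosomal protein mRNAs had a median of 0.45 in both lists, but by edgeR 0 rose and 1 fell in the 40S list (RPS9A, from 160 ± 16.1 to 32.9 ± 14.5 CPM, -2.12 ± 0.25), and 0 passed in the 60S list. In the 40S list 20 had an unadjusted p under 0.05, DESeq2 called 13 and limma-voom 2. In the 60S list 30 had an unadjusted p under 0.05, DESeq2 called 24 and limma-voom 2. Adjusted over the list alone the edgeR counts were the same. RPL3 and RPL10 had 0.92 ± 0.34 and 0.75 ± 0.28. Camera gave adjusted p = 1.74e-05 and 3.41e-07, and adjusted p = 0.887 for both with an estimated correlation. Without ΔES7S replicate 2 the medians were 0.27 and 0.26, without WT replicate 2 that of the 40S list was 0.27, and without ΔES7S replicate 1, 17 and 26 genes rose and 4 and 6 fell. Initiation factors had a median of 0.17 with 0 of 33 changed by edgeR, also when adjusted over the list alone (11 had an unadjusted p under 0.05, DESeq2 called 6 and limma-voom 0). PAB1 and FUN12 had 0.65 ± 0.29 and -0.51 ± 0.19. Their camera adjusted p was 0.0277, 0.887 with an estimated correlation, 0.0885 without WT replicate 2 and 0.0706 without ΔES7S replicate 1.

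Of the mRNAs of 40S assembly factors 0 of 75 passed by edgeR (7 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma-voom), with a median of -0.11 and camera adjusted p = 0.824. NOP1, fibrillarin, had 0.33 ± 0.24. Of those for the 60S subunit 1 of 74 rose (REH1 0.89 ± 0.16), with a median of 0.02 (-0.06 with upper-quartile scaling) and adjusted p = 0.529. Adjusted over the list alone the counts of both lists were the same. The ΔES7S mRNA libraries disagreed. Relative to WT the mean level in replicates 1, 2 and 3 was 0.20, -0.18 and -0.35 for the 40S list. For the 60S list it was 0.26, -0.08 and -0.23 (WT SD 0.14 and 0.16). Further lists with 1 changed mRNA were glycolysis (TDH2 -1.40 ± 0.28), the proteasome (RPN8 1.03 ± 0.17), ER protein folding (ULI1 -2.51 ± 0.36), amino acid synthesis (ARG3 -1.22 ± 0.24, and 3 lower adjusted over the list alone), the phosphate regulon (PHO5; 4 higher and 2 lower adjusted over the list alone), pheromone genes (SST2 -1.08 ± 0.18) and meiosis genes (SMK1 -2.07 ± 0.30). Lists with 0 changed mRNAs by edgeR were RNA polymerase I and III, elongation factors, synthetases, quality control, the TCA cycle, heat shock chaperones, the stress response, methionine, ergosterol, hexose transport, histones, G1 and S phase, and frameshift genes. Over these 13 lists 89 of 363 genes had an unadjusted p under 0.05, DESeq2 called 54 and limma-voom 6. By edgeR 2 elongation factors, 2 methionine genes and 1 frameshift gene passed when adjusted over the list alone. Camera adjusted p for the uncalled mRNA lists ran from 0.101 to 0.863. In the stress lists, where footprints rose, mRNA medians were -0.06 for the stress response and -0.19 for the chaperones, and HSP82 mRNA had -1.50 ± 0.35 (adjusted p = 0.0567).

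**Figure D2:**
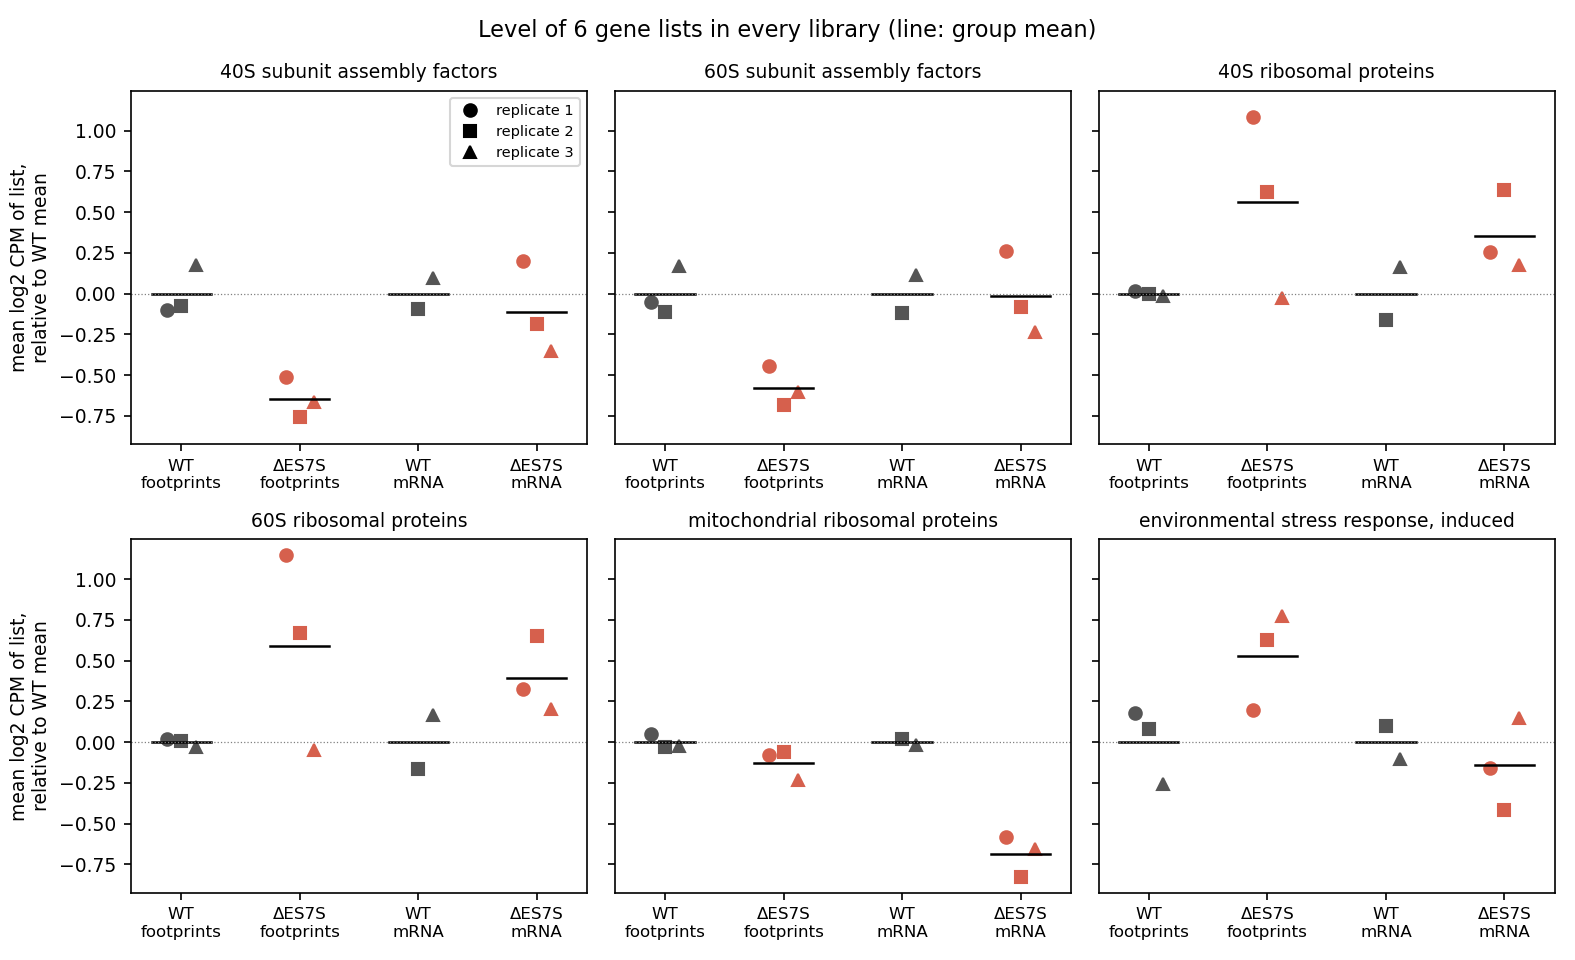
Mean log2 CPM of 6 gene lists in every library, relative to the WT mean of the same assay (y axis), with symbols for replicates and a line at each group mean. Assembly factor footprints lie between -0.75 and -0.44 in the 3 ΔES7S libraries, mitochondrial ribosomal protein mRNA between -0.83 and -0.58, and cytosolic ribosomal protein footprints range from -0.05 to 1.15.

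Footprint and mRNA changes, which come from different libraries, were related across the 5433 genes tested in both: Pearson r was 0.326 and Spearman rho 0.308 across genes (genes are not independent replicates). The total least squares slope of footprint on mRNA change was 0.658, and 59.7% of genes had the same sign. Of genes called in both, 51 rose in both, against 9.55 if the calls were independent, 26 fell in both, against 11.02, and 1 rose in footprints and fell in mRNA. These counts rest on the 155 mRNA calls, which were 0 by edgeR without WT replicate 2 or 3 or ΔES7S replicate 2 or 3 (660, 766, 1344 and 1034 at an unadjusted p under 0.05).

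**Figure D3:**
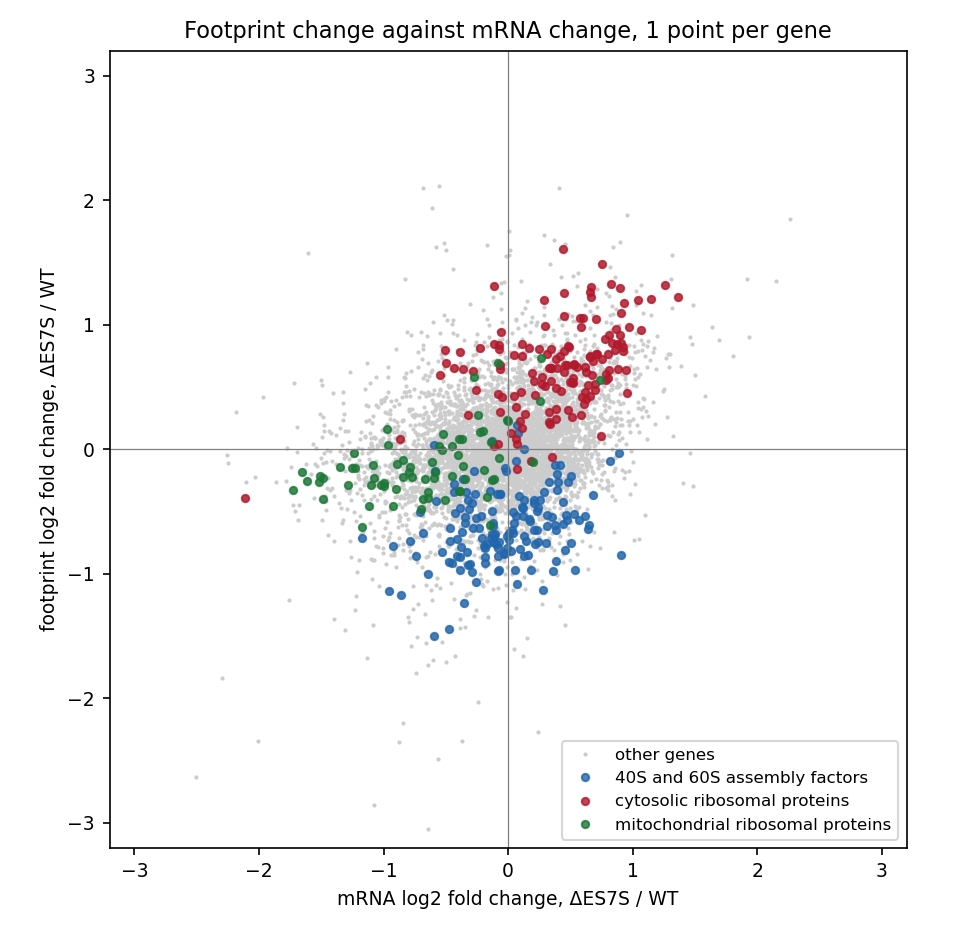
Footprint log2 fold change (y axis) against mRNA log2 fold change (x axis), ΔES7S over WT, for 5433 genes, 1 point per gene. Assembly factors (blue) lie at a footprint median of -0.64, cytosolic ribosomal proteins (red) at list medians of 0.66 in footprints and 0.45 in mRNA, and mitochondrial ribosomal proteins (green) at -0.18 and -0.64.

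The third comparison asks where footprints per mRNA, the translation efficiency, differed between the strains. Of 149 ribosome assembly factors 46 fell and 0 rose, of 49 stress response genes 11 rose and 0 fell, and of 69 mitochondrial ribosomal protein genes 19 rose and 0 fell. Camera called these lists at the preset correlation, and with an estimated correlation their adjusted p was 0.658. The mitochondrial list had lower mRNA (median -0.64) and no higher footprints (median -0.18). GCN4 (YEL009C) had 3.75-fold fewer footprints per mRNA, and OLE1 (YGL055W, fatty acid desaturase) was 3.29-fold lower. GIP2 (YER054C) was up 8.68-fold, HXK1 6.18-fold and PGM2 4.37-fold. Over 5588 genes edgeR called 501, 259 higher and 242 lower, and 150 and 104 by at least 2-fold (1621 had an unadjusted p under 0.05). Upper-quartile scaling moves the median of all genes by 0.108 and gives 278 higher and 139 lower. The number of genes was 11 or 31 without WT mRNA replicate 2 or 3, and 305, 132 or 69 without WT footprint replicate 1, 2 or 3. It was 1848, 322 or 225 without ΔES7S mRNA replicate 1, 2 or 3, and 325 or 83 without ΔES7S footprint replicate 1 or 2. With all libraries DESeq2 called 903. The counts of list members below move with it.

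Efficiency fell on 22 of 75 assembly factors of the 40S subunit and on 24 of 74 of the 60S subunit, 0 rose, and 53 and 50 did not pass (40 and 39 fell when adjusted over the list alone). HCA4 had -1.45 ± 0.21 (SE; adjusted p = 0.0076), the GTPase NOG1 -1.55 ± 0.27, NSA2 -1.30 ± 0.22 and the helicase DRS1 -1.38 ± 0.24 (adjusted p = 0.0124, 0.0115 and 0.0119), and NSR1, outside the lists, -1.70 ± 0.31. The medians were -0.65 and -0.67, both with camera adjusted p = 4.86e-13, and adjusted p = 0.658 with an estimated correlation. The 22 and 24 members ranged from 0 without WT mRNA replicate 2 to 32 and 36 without ΔES7S mRNA replicate 1. RNA polymerase I and III had 4 of 36 lower, 1 higher and 31 not past the test (7 and 1 adjusted over the list alone; RPA190 -1.15 ± 0.26, TFC3 0.71 ± 0.15). Its median was -0.24, with adjusted p = 0.0462, adjusted p = 0.732 with an estimated correlation, and from 0.0957 to 0.403 without WT mRNA replicate 2, WT footprint replicate 3, ΔES7S mRNA replicate 1 or ΔES7S footprint replicate 2. The polymerase median ran from -0.13 (without ΔES7S mRNA replicate 2) to -0.28 (without WT footprint replicate 1).

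Of 33 initiation factors 4 fell, 1 rose and 28 did not pass (5 and 1 adjusted over the list alone), with TIF4631 (eIF4G) at -1.34 ± 0.31, NIP1 (eIF3) at -1.18 ± 0.23, GCN3 (eIF2B) at -0.82 ± 0.22 and GCN1 at 0.70 ± 0.20. The median was -0.29, adjusted p = 0.00151, and 0.658 with an estimated correlation. Of 32 elongation and termination factors 5 fell, 0 rose and 27 did not pass (6 adjusted over the list alone), with RBG1 at -1.09 ± 0.22 and the diphthamide synthesis genes DPH2 and DPH1 at -0.89 ± 0.21 and -0.74 ± 0.18. Their median was -0.23, adjusted p = 0.0121, adjusted p = 0.658 with an estimated correlation, and 0.056 without WT mRNA replicate 2. Their median ran from -0.11 (without ΔES7S mRNA replicate 2) to -0.35 (without ΔES7S footprint replicate 1). GCN4 went from 285 ± 64.3 to 102 ± 18.9 CPM in footprints (SD, n = 3 each) and from 2479 ± 79.4 (n = 2) to 2946 ± 90.1 CPM (n = 3) in mRNA, an efficiency change of -1.91 ± 0.32 (adjusted p = 0.0117). In the list of frameshift and leader-ORF genes that holds it, 5 of 19 fell, 0 rose and 14 did not pass (5 lower and 1 higher adjusted over the list alone), with HAP4 at -1.13 ± 0.20. The median was -0.28, camera adjusted p = 0.0632, adjusted p = 0.658 with an estimated correlation, and fry 0.0181. Of the 54 amino acid biosynthesis genes 2 fell (GCN4 itself and LYS20, at -0.94 ± 0.25) and 1 rose (BAT2, 0.79 ± 0.22), with a median of -0.10 (0.01 with upper-quartile scaling) and adjusted p = 0.0632. Adjusted over the list alone 1 fell.

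Of 49 stress response genes 11 rose in efficiency, 0 fell and 38 did not pass (13 higher and 1 lower adjusted over the list alone), and of 28 chaperones 5 rose, 0 fell and 23 did not pass (6 adjusted over the list alone). PGM2 had 2.13 ± 0.34 (adjusted p = 0.00937), GSY1 1.69 ± 0.26, HSP42 1.86 ± 0.34 and HSP82, an Hsp90 gene with a close copy in HSC82, 2.02 ± 0.50 (adjusted p = 0.0329). The medians were 0.55 and 0.50, with camera adjusted p = 8.51e-06 and 7.3e-05, and adjusted p = 0.658 for both with an estimated correlation. HXK1, with 150 ± 46.6 against 618 ± 95.4 CPM in footprints (SD, n = 3 each) and 558 ± 23.5 (n = 2) against 332 ± 71.6 CPM (n = 3) in mRNA, had 2.63 ± 0.34 (adjusted p = 0.00591). GIP2 had 3.12 ± 0.55 (adjusted p = 0.0124), and YJR149W and YIR016W had 2.75 ± 0.25 and 2.14 ± 0.29. Stress gene counts ranged from 1 without WT mRNA replicate 2 to 14 without ΔES7S mRNA replicate 1, and chaperone counts from 0 without either WT mRNA library to 6.

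Efficiency rose on 19 of 69 mitochondrial ribosomal protein genes, 0 fell and 50 did not pass (31 adjusted over the list alone). The median was 0.48, with camera adjusted p = 9.52e-10, adjusted p = 0.658 with an estimated correlation and 0.0181 by fry. Footprints of this list did not rise (median -0.18, 4 higher and 10 lower). The efficiency value thus rests on the mRNA fall (median -0.64) in the same mRNA libraries and is no separate result. MRPL35 had 1.36 ± 0.26 (adjusted p = 0.0138), RSM19 1.22 ± 0.24 and MRP2 0.96 ± 0.17. The count ranged from 0 without either WT mRNA library to 34 without ΔES7S mRNA replicate 1, while the median stayed between 0.44 and 0.55. PET117, a cytochrome oxidase assembly factor, had 23.2 ± 3.17 (SD, n = 2) against 5.22 ± 1.08 CPM (n = 3) in mRNA and 28.6 ± 4.27 against 36.1 ± 0.41 CPM in footprints (n = 3 each), an efficiency change of 2.34 ± 0.22 (adjusted p = 0.00025). DPC29, a mitochondrial protein, had 2.15 ± 0.37, and RPS9A, whose mRNA fell, 1.69 ± 0.30 (adjusted p = 0.0124).

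Of 27 genes for secreted and GPI-anchored proteins 1 fell (phospholipase gene PLB1, -0.79 ± 0.21), 0 rose and 26 did not pass (0 adjusted over the list alone by edgeR). Negative values numbered 25 of 27, the median was -0.57, adjusted p = 0.000174, and 0.658 with an estimated correlation. With 1 library left out it ran from -0.30 (without ΔES7S mRNA replicate 2) to -0.70 (without ΔES7S mRNA replicate 1). Footprints of the secreted list did not fall (median 0.24, 8 higher and 1 lower). Its efficiency value thus rests on the higher mRNA (median 0.68) and is no separate result. Of 25 cell wall integrity genes 1 rose (KDX1, 0.93 ± 0.24) and 24 did not pass, also adjusted over the list alone. The median was -0.44, adjusted p = 0.0342, 0.658 with an estimated correlation, and 0.0613, 0.0768 and 0.114 without WT mRNA replicate 2, WT footprint replicate 2 and ΔES7S footprint replicate 3. The cell wall median ran from -0.26 (without ΔES7S mRNA replicate 2) to -0.56 (without ΔES7S mRNA replicate 1). Cell wall footprints did not fall either (median 0.24, 6 higher and 0 lower), and this value likewise rests on the higher mRNA (median 0.55). Of 27 TCA cycle genes 2 fell (among them malate synthase MLS1, -1.77 ± 0.49), 1 rose (MDH2 1.21 ± 0.27) and 24 did not pass, also adjusted over the list alone. Its median was -0.39, adjusted p = 0.0243, 0.658 with an estimated correlation, and 0.175, 0.0694 and 0.0509 without WT mRNA replicate 3, ΔES7S mRNA replicate 3 and ΔES7S footprint replicate 1. The TCA median ran from -0.20 (without WT mRNA replicate 3) to -0.59 (without ΔES7S mRNA replicate 1). Of 40 respiratory chain genes 1 rose (CYC7, 1.05 ± 0.27) and 39 did not pass (0 passed adjusted over the list alone by edgeR). The median was -0.25, adjusted p = 0.0235, 0.732 with an estimated correlation, and 0.0817, 0.0679 and 0.114 without WT footprint replicate 1, ΔES7S mRNA replicate 3 and ΔES7S footprint replicate 3. The respiratory chain median ran from -0.13 (without ΔES7S footprint replicate 3) to -0.38 (without ΔES7S footprint replicate 1). Its footprint median was 0.009 and its mRNA median 0.21, so that this value too rests on the mRNA.

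Among the other large efficiency falls, IMD2 had -2.56 ± 0.44 (adjusted p = 0.0119; footprints 2203 ± 244 against 435 ± 117 CPM, SD, n = 3 each, and mRNA 58.3 ± 15.5, n = 2, against 58.9 ± 15.9 CPM, n = 3). OLE1 had 1070 ± 131 against 356 ± 85.1 CPM in footprints, an efficiency change of -1.72 ± 0.31, and the biotin synthase gene BIO2 had -1.71 ± 0.22. SST2, which limits pheromone signalling, had -1.82 ± 0.29, SRO9, an RNA-binding protein of translating ribosomes, -1.82 ± 0.30, YBR238C -1.83 ± 0.40 and FIT2 -1.72 ± 0.35. Ribosomal protein lists had medians of 0.15 and 0.11 in efficiency, with 1 of 57 (RPS9A) and 0 of 81 changed by edgeR, also adjusted over the list alone. In the 60S list 11 had an unadjusted p under 0.05, DESeq2 called 4 and limma-voom 0. Camera adjusted p was 0.304 and 0.329. Changed genes, higher and lower, numbered 0 and 3 of 28 in the iron list (ARN1 -1.64 ± 0.29) and 1 and 1 of 19 in hexose transport (HXT7 2.50 ± 0.39, ADH2 -1.66 ± 0.40). They were 2 and 2 of 37 in quality control (FAP1 -1.41 ± 0.21), 1 and 0 of 21 in glycolysis (HXK1) and 1 and 1 of 35 in the proteasome (PRE6 1.52 ± 0.42, RPN8 -0.88 ± 0.23). ER folding had 0 and 1 of 28 (LHS1 -0.75 ± 0.20), and 0 and 2 of 33 passed in G1 and S phase (CDC6 -0.89 ± 0.22, SWI4 -0.72 ± 0.19; median -0.23, mean 0.01). Synthetases, methionine, ergosterol, phosphate, histone and meiosis genes had 0 of 118 genes changed by edgeR (27 at an unadjusted p under 0.05, 13 by DESeq2 and 1 by limma-voom), and 2 histone genes passed when adjusted over the list alone. Camera adjusted p for these 13 lists ran from 0.134 to 0.743. Over the 3 comparisons camera called 15, 8 and 13 of 32 lists at the preset correlation and 0, 0 and 0 with an estimated correlation, where 1, 1 and 1 had an unadjusted p under 0.05. Fry called 5, 0 and 3.

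**Figure D4:**
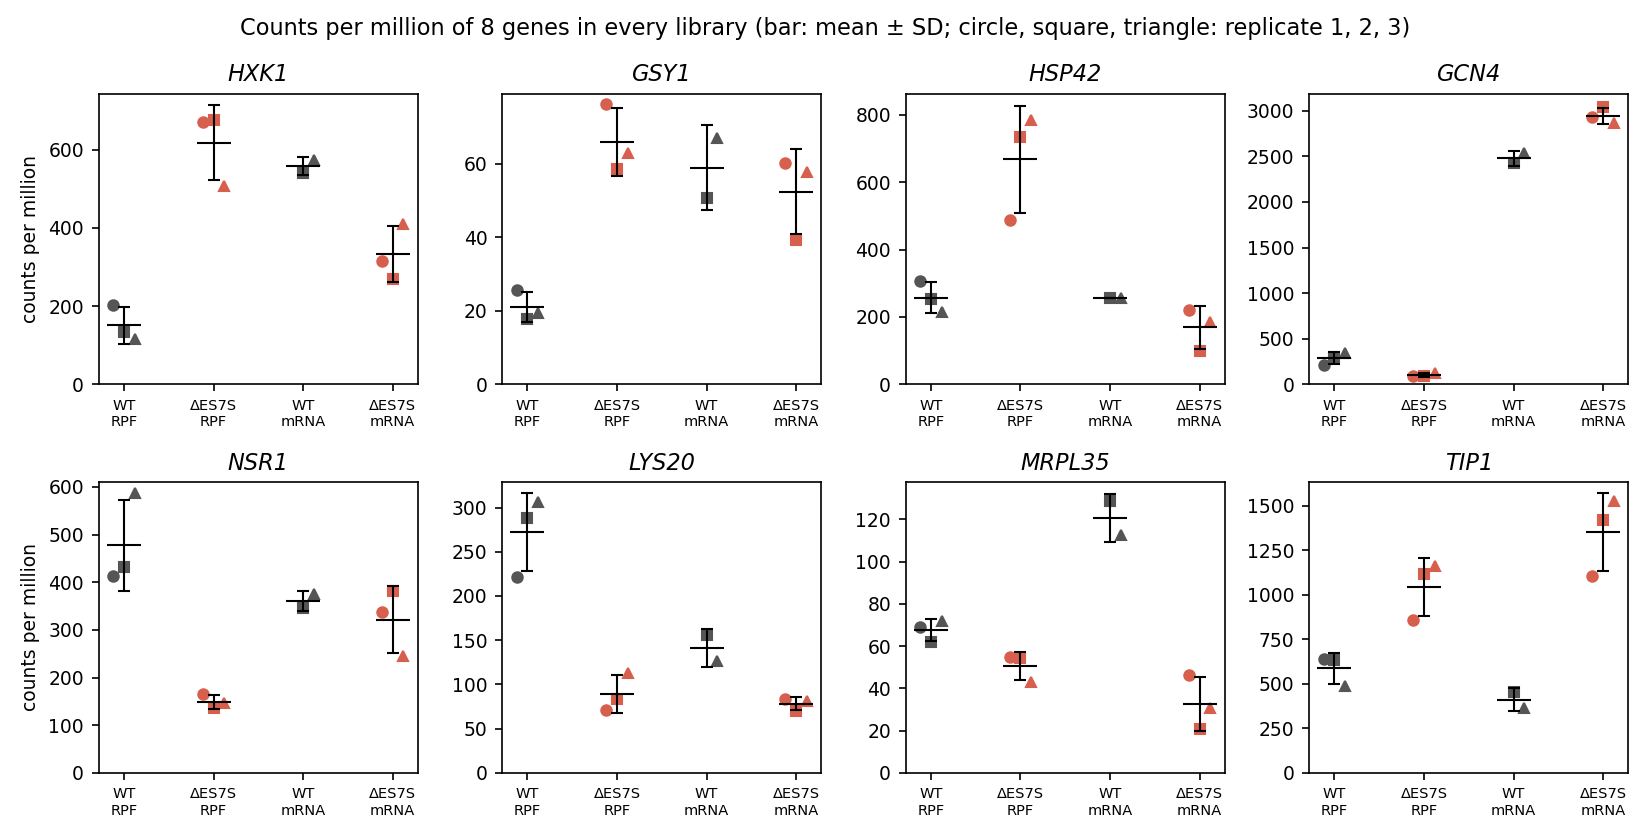
CPM (y axis, from 0) of 8 genes in every library, with symbols for replicates 1, 2 and 3 and bars for mean ± SD of each group. HXK1 footprints went from 150 to 618 CPM while its mRNA had 558 and 332 CPM, and GCN4 footprints went from 285 to 102 CPM while its mRNA had 2479 and 2946 CPM.

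Mating-type and auxotrophic markers were read in every library as a check of the strains' background. The a-cell genes STE2, the pheromone receptor, and MFA2 had 94.8 to 165 and 63.9 to 70.5 CPM in footprints and 164 to 259 and 63.4 to 77.2 CPM in mRNA. MFA1, STE6, BAR1, AGA2 and ASG7 had 15.6 to 32.4, 67.8 to 81.9, 14.4 to 35.9, 12.1 to 23.4 and 5.18 to 8.61 CPM in footprints, and 15.9 to 36.3, 67.4 to 96.1, 7.12 to 29.6, 10.3 to 42.9 and 6.59 to 7.56 CPM in mRNA. The mRNA ranges of WT and ΔES7S did not overlap for STE2 (234 to 259 against 164 to 205 CPM). Nor did they for BAR1 (25.6 to 29.6 against 7.12 to 17.0) and AGA2 (39.2 to 42.9 against 10.3 to 25.5). Those of MFA1, MFA2, STE6 and ASG7 overlapped. The alpha-cell genes MF(ALPHA)1, MF(ALPHA)2 and STE3 stayed at or below 1.09, 0.441 and 6.78 CPM in both assays. SAG1 and AFB1 had 3.60 to 8.69 and 7.16 to 13.4 CPM in footprints and 41.8 to 49.6 and 21.8 to 42.1 CPM in mRNA. In footprints 3 of 7 a-cell genes fell (MFA1 -0.75 ± 0.14, BAR1 -0.77 ± 0.15, STE2 -0.40 ± 0.13) and 1 rose (ASG7 0.57 ± 0.18; the same counts adjusted over the list alone; camera adjusted p = 0.344). In footprints 0 of 3 alpha-cell genes tested by edgeR passed (0 at an unadjusted p under 0.05, and 0 by DESeq2 or limma-voom). In mRNA 0 of 7 and 0 of 4 passed by edgeR (2 and 1 at an unadjusted p under 0.05, 2 and 1 by DESeq2, 0 and 0 by limma-voom), with 2 a-cell genes lower adjusted over the list alone. In efficiency 0 of 7 and 0 of 4 passed by edgeR (0 and 1 unadjusted, 0 by DESeq2 or limma-voom). Of 19 haploid and pheromone genes 4 fell in footprints, among them SST2 (-2.85 ± 0.24) and FIG2 (-1.35 ± 0.30), and 1 rose (4 and 2 adjusted over the list alone; camera adjusted p = 0.16, fry 0.0181). In efficiency 2 fell and 1 rose (FUS2 1.43 ± 0.40; 3 and 1 adjusted over the list alone).

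The auxotrophic markers URA3 and TRP1 had 7698 to 14244 and 11530 to 16061 CPM in footprints. In mRNA URA3 had 21088 to 23488 CPM in WT and 6902 to 9858 CPM in ΔES7S (-1.26 ± 0.26, adjusted p = 0.0524), and TRP1 14741 to 16238 CPM in WT and 9993 to 11832 CPM in ΔES7S. LEU2 mRNA fell, with 26.7 and 27.4 CPM in the WT libraries and 5.22 to 12.8 CPM in ΔES7S (-1.46 ± 0.28, adjusted p = 0.0444). ADE2 mRNA had 67.6 to 73.0 against 5.17 to 29.0 CPM (-2.19 ± 0.56, adjusted p = 0.0673). In footprints LEU2, HIS3, ADE2, ADE3, LYS2, MET17 and CAN1 had 27.6 to 56.1, 342 to 537, 48.1 to 70.4, 624 to 945, 237 to 281, 957 to 2318 and 28.4 to 32.4 CPM. In mRNA HIS3, ADE3, LYS2, MET17 and CAN1 had 439 to 705, 336 to 794, 173 to 302, 257 to 833 and 33.8 to 113 CPM. The mRNA ranges of the strains did not overlap for HIS3 (678 to 705 CPM in WT, 439 to 496 in ΔES7S). Nor did they for ADE3 (736 to 794 against 336 to 575) and CAN1 (94.2 to 113 against 33.8 to 84.4). Those of LYS2 and MET17 overlapped. As a list, 0 of 9 markers changed in footprints by edgeR, also adjusted over the list alone (2 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma-voom), with camera adjusted p = 0.846. In mRNA 1 of 9 fell, 5 adjusted over the list alone, and all 9 values were negative, with a median of -0.63, adjusted p = 0.00148 and adjusted p = 0.811 with an estimated correlation. In efficiency 1 rose (ADE2, 2.45 ± 0.58, adjusted p = 0.0293), 4 adjusted over the list alone, with a median of 0.60, adjusted p = 0.0109, adjusted p = 0.658 with an estimated correlation and 0.0253 by fry.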

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

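In this part the tests of the ribosomal protein share, of a single outlying library and of a shared fall of ribosomal protein and assembly genes were chosen only after the result was seen. For 7 gene lists the median change went opposite ways in footprints and mRNA while the interaction test (camera on translation efficiency, preset correlation) had an adjusted p under 0.05. The median efficiency changes were -0.67 for 60S assembly factors (footprints -0.61, mRNA 0.02), -0.24 for RNA polymerase I and III (-0.20 and 0.02), -0.29 for initiation factors (-0.12 and 0.17), -0.23 for elongation and termination factors (-0.05 and 0.14) and -0.39 for the TCA and glyoxylate cycle (-0.18 and 0.14). They were 0.50 for heat shock chaperones (footprints 0.43, mRNA -0.19) and 0.55 for the induced stress response (0.45 and -0.06). The mRNA medians near 0 carry no direction of their own, since those of 60S assembly factors and RNA polymerase I and III turned to -0.06 and -0.05 with upper-quartile scaling. Camera called elongation factors in neither assay (adjusted p = 0.245 in footprints and 0.101 in mRNA) and initiation factors not in footprints (0.16). In mRNA it did not call the TCA cycle or the heat shock chaperones (adjusted p = 0.459 and 0.526). For the TCA list the mean mRNA level ran from -0.04 to 0.26 over the ΔES7S libraries (WT SD 0.19). For the chaperones it ran from -0.33 to -0.05 (WT SD 0.01). The mean mRNA level of the stress list ran from -0.42 to 0.15 over the ΔES7S libraries, so that its mRNA direction is open too. With an estimated correlation the adjusted p of these 7 lists ran from 0.658 to 0.732.

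Of the 149 assembly factor genes 114 fell in footprints and 0 rose, with a median of -0.64, while the mRNA medians of the 40S and 60S lists were -0.11 and 0.02. The mean mRNA levels of these lists ran from -0.35 to 0.20 and from -0.23 to 0.26 over the ΔES7S libraries. Their mRNA direction is thus open, and with it how much of the footprint fall follows mRNA. Ribosomal protein reads that take a larger part of a library would lower all other genes. The highest share in a ΔES7S footprint library (11.2%) could change them by only -0.091 in counts without TMM factors. That is a smaller change than the median of -0.64 in the TMM-scaled fits, and too small to be the whole cause. A planned refit without those genes gave -0.63, but moved the other genes too little to decide. With each library left out in turn, the median nearest to 0 was -0.53, so that the fall did not hang on any 1 library. The limits of both tests were set after the values were seen, so that only these sizes count. Ribosomal protein footprints were not lower by 0.3 or more together with those of assembly genes. The lowest mean level of a ribosomal protein list in a ΔES7S footprint library was -0.048. The limit of this test was set after these levels were seen, so that it does not decide on slower growth or a later harvest. A growth difference stays open, since 23 of 49 stress response genes rose and 11 of 36 RNA polymerase I and III genes fell. A lower translation of assembly factor mRNAs in ΔES7S cells also stays open as a hypothesis found and tested on the same data, beside culture or library batches, which the labels do not give.

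The 6 footprint libraries make 10 splits of 3 against 3, too few for a share under 0.05. For genes called, 1 of the 10 splits reached the real count of 1463, and the highest other split gave 0 by edgeR. For gene lists called at the preset correlation, 4 of the 10 splits reached the real count of 15, and the highest other gave 17, with WT replicates 1 and 3 and ΔES7S replicate 1 on 1 side.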

How the results depend on the processing

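Nothing in this part was chosen after the result was seen. Of gene counts in footprints (1463), 9 alternatives gave 1090 (joint fit of all libraries) to 1563 (DESeq2), 177 changed by at least 2-fold, and leaving out 1 library gave 684 to 1749. In mRNA (155) the other scalings, filters and the fit without ribosomal protein genes gave 118 to 170, a 2-fold minimum 95, DESeq2 1036, limma-voom 327, the joint fit 1463, and leaving out 1 library 0 (edgeR; 660 at an unadjusted p under 0.05 without WT replicate 2) to 2467. In efficiency (501) scalings, limma-voom, filters and the fit without ribosomal protein genes gave 417 to 535, a 2-fold minimum 254, DESeq2 903, only numbers with both assays 305, and leaving out 1 library 11 to 1848. Where 1 library was left in a group, it was assumed to vary like the others. Lists called numbered 15, 8 and 13 in footprints, mRNA and efficiency. RLE scaling gave the same numbers, leaving out 1 library 12 to 14, 8 to 12 and 12 to 16, an estimated correlation 0, 0 and 0 (1, 1 and 1 at an unadjusted p under 0.05), and fry 5, 0 and 3. The correlation of footprint and mRNA changes (0.326) ran from 0.281 to 0.373. Apart from the smaller samples and the added 2-fold minimum, the cause was not tested. Of 1087, 363 and 1134 repeats of named genes in footprints, mRNA and efficiency, 1031, 253 and 913 kept direction and side of the threshold. The others lost the call, and 0 turned around. For the largest efficiency changes the naming rule already fixed the sign whichever library was left out, so that those repeats could not turn around. For the largest footprint and mRNA changes the rule required every ΔES7S library on the same side of every WT library. Leaving out 1 library could hardly turn those around either. For lists 110 of 150, 53 of 72 and 155 of 195 were kept. The alternative for near-identical copies (25-mers shared between genes) was not run, since no sequences were used here. At a 1.5-fold change simulated genes were recovered at 59.7%, 11.9% and 7.46%, which limits what the smaller mRNA and efficiency counts can show.

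Whether replicate numbers pair the samples could not be decided. Deviations of same-numbered footprint libraries from their group means correlated at 0.01, 0.20 and 0.09, and of mRNA libraries at -0.15 and -0.66. WT footprint replicates 2 and 3 correlated best with their own number in ΔES7S, but WT footprint replicate 1 did not (0.09 with ΔES7S replicate 2). Deviations within groups of 2 or 3 libraries are tied to each other (-1 between the WT mRNA libraries), so that these values are a weak check. Same-numbered mRNA and footprint libraries of a strain correlated at 0.20 and 0.04 (WT 2 and 3) and 0.05, -0.04 and 0.43 (ΔES7S 1 to 3). A replicate block gave 1341, 1924 and 704 genes and 15, 7 and 11 lists, and a culture block 306 genes in efficiency. In mRNA ΔES7S replicate 1 is the only library with its number, so that the block fits it exactly and takes it out of the contrast. The 1924 genes therefore stand beside the 2467 called without that library and without a block, and are no measure of replicate batches. Under the replicate block, initiation factors in mRNA and RNA polymerase I and III and the respiratory chain in efficiency were not called (adjusted p = 0.0564, 0.103 and 0.0638).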

Other observations

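In this part 4 added gene lists, the genes IMD3, IMD4 and MEF1, and the tests of a general loss of mitochondrial mRNAs, of the axis between ΔES7S mRNA libraries and of a fall shared with other mitochondrial mRNAs were chosen only after the result was seen. Of 21 genes of glycogen and trehalose metabolism, 12 of which are in the lists above, 16 rose in footprints, 0 fell and all 21 values were positive, with a median log2 fold change of 1.02. The list was drawn after rises of members such as GSY1 and PGM2 had been seen, so that these values are no test of it. Their mRNA had a median of 0.10 and their efficiency 0.53, with 6 genes higher. Of 31 genes of mitochondrial protein import 1 fell in mRNA (median -0.21, camera adjusted p = 0.0132, and 0.175 with an estimated correlation). In footprints 3 of them fell and 0 rose (median -0.09, camera adjusted p = 0.0729), and in efficiency 1 rose and 0 fell (median 0.02, camera adjusted p = 0.429). IMD3 and IMD4, which resemble IMD2, fell in footprints from 1079 ± 85.1 to 591 ± 18.9 and from 403 ± 50.9 to 179 ± 0.81 CPM (SD, n = 3 each; -0.79 and -1.10), with mRNA changes of -0.05 and -0.20.

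Of 69 mitochondrial ribosomal protein mRNAs 21 fell by edgeR, with a list median of -0.64 (camera adjusted p = 2.21e-13 at the preset correlation, and 0.811 with an estimated correlation). The fall did not reach the respiratory chain list, with a median of 0.21 and 0 of 40 mRNAs lower. The limit for this test was set after that value was seen, so that a loss of most other nuclear-encoded mitochondrial mRNAs stays open. In the added list of protein import the median was -0.21. The ΔES7S mRNA libraries differ from each other along principal component 1 (79.7% of the variance, with values of -6.48, 32.8 and 14.9 in replicates 1 to 3 against -21.3 and -19.9 in WT), and a line through these 3 libraries gives a level of -0.48 at the WT position (95% interval -1.29 to 0.34), too wide to decide whether that axis is the cause. A fall shared with mRNAs for mitochondrial gene expression and respiratory assembly outside the ribosome stays open, since the 2 added lists were drawn after falls of members such as OXA1 and SDH7 had been seen, so that their joint median of -0.65 is no test of it. In 37 genes of mitochondrial gene expression 8 mRNAs fell (median -0.62) and in 32 respiratory assembly factors 9 fell (median -0.71). Their footprint medians were -0.15 and -0.003, and their efficiency medians 0.35 and 0.68. MEF1, a mitochondrial elongation factor, had an mRNA change of -2.03 ± 0.44 (adjusted p = 0.0542). Whether the strain or an unrecorded batch lowered these mRNAs stays open and was not tested.

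Ribosomal protein footprints were higher in ΔES7S by list medians of 0.66, but unevenly, with levels for the 60S list of 1.15, 0.67 and -0.05 in replicates 1 to 3. Unprotected mRNA fragments in replicate 1 would also raise genes with few footprints per mRNA in WT, but 497 such genes differed between replicates 1 and 3 by a median of 0.011 (quartiles -0.28 and 0.29), against 1.17 for ribosomal protein genes, which argues against this as the whole cause. A smaller share of such fragments stays open, since replicate 1 correlated with the mRNA libraries at r from 0.717 to 0.791, against 0.635 to 0.730 for replicate 3, and lay nearer to them on principal component 1 of all libraries (23.7, against 30.5 to 35.1 in the other footprint libraries). Reads shared between duplicated genes are argued against by the 20 ribosomal protein genes without a copy, whose median was 0.74, with all 20 positive, against 0.65 for 118 genes with one. A difference in growth between the ΔES7S cultures stays open and was not tested.

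Genes of the mitochondrial genome took 0.0109% of counts in ΔES7S footprint replicate 2, against 0.00224% to 0.00406% in the other footprint libraries. Principal component 2 of the footprint libraries (22.9% of the variance) parted the ΔES7S replicates, at 12.3, -1.52 and -15.8.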
